A study of Caenorhabditis elegans with 6 samples.

How the data were processed

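RNA-seq counts of 6 libraries were analysed, 3 from N2 and 3 from spr-5; met-2 starved L1 larvae of Caenorhabditis elegans, grouped and numbered by their titles. Per the labels' protocols, animals were grown on bacteria of strain HT115 at 20 °C, and total RNA was taken with TRIzol from about 1000 to 1500 larvae that hatched overnight in buffer at 21 to 22 °C.

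The deposited count tables hold whole-number counts per RefSeq transcript record, not normalized. Per the submitters' processing notes, FastQC, Trimmomatic, featureCounts and DESeq2 2.11.40.2 and the build ce10 were used, with no role or order given. Per the file headers the reads were aligned with HISAT2, and the headers also carry the vector name L4440, which no label mentions. Strand setting, treatment of reads shared between records and library kit are not given in the sources used here. The authors' deposited comparison table gives a base mean signal (a mean over libraries of counts divided by size factors), a log2 fold change, a standard error and a Wald statistic (both scores without a fixed range), a p-value and an adjusted p-value per record, per the file headers.

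Each table held 50832 records, 28376 of them for mRNA and 22456 for non-coding RNA. A RefSeq gene table of assembly WBcel235 named 46074 records of 39875 genes by their transcript identifiers. The other 4758 records kept their place in library sizes and tests but are not named in the text, and named records held 86.6% to 87.2% of counts. Of the named genes 3590 had several records. Of their 9789 records 62.1% had 0 counts in all libraries, and the median summed count of such protein-coding genes was 78 against 524 for genes with a single record. Reads that fit several records may thus be missing from the counts, so genes with several records, close paralogs and overlapping or antisense neighbours are uncertain. Chromosomes and exonic lengths came from an Ensembl annotation of WBcel235, matched by gene name and, for lengths, also by sequence name. That build differs from the authors', so no coordinates are given.

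Total counts ranged from 17062557 to 25368364 per library. Records were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 14557. Libraries were scaled by TMM, with factors of 0.827, 0.957 and 0.999 for N2 and 1.07, 1.06 and 1.11 for spr-5; met-2 in replicates 1 to 3. The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested records and a threshold of 0.05. CPM values are TMM-normalised and given as mean ± SD over 3 libraries, and the SE of a log2 fold change is its size divided by the square root of the F statistic. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the whole group (0.0514 CPM for N2 and 0.0457 CPM for spr-5; met-2). With 1 to 3 counts the ratio is given with an exact conditional 95% interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

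Before the data were examined, 23 gene lists and 15 families defined by gene name were fixed, along with the design and the alternatives. They were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 and adjustment over the 35 lists with at least 3 tested members, using the record with the highest mean CPM per gene. With 2 tested members the vitellogenin list was not tested, the major sperm protein family had no tested member, and no record matched the list of mitochondrially encoded genes. The genes named are spr-5 and met-2; htp-1, cpb-1, pgl-1, glh-1 and mes-4; the 10 largest rises and 10 largest falls among records past the threshold with at least 5 CPM in the higher group and no overlap between groups; up to 4 members of each list or family with the smallest adjusted p; and the most abundant member of a list without a call. The X chromosome was compared with the autosomes by Fisher's exact test.

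The alternatives were DESeq2's size factors within edgeR, library size only, no count filter, a filter of 1 CPM in 3 libraries, DESeq2 (1.42.0), limma voom, the replicate number as a block, each library left out in turn, a 2-fold minimum, an adjusted p below 0.01, and for lists an estimated correlation and fry. Camera tests a list against the other genes and fry against no change, so the ranges given over alternatives hold both questions where fry is among them. Medians marked voom are those of the alternatives and can differ from the edgeR medians. Summing records per gene and removing a smooth trend with exonic length per library, in the fit with the block, were added after the data were seen. An earlier spline form of the length trend was replaced by a robust local fit because it shifted the median of all records. Length matching was then extended by sequence name, because too few ribosomal protein genes had a length. This moved their corrected median above a bound of -0.3 that had been set before the extension, and the bound was left as written. The comparison of vitellogenin with the P granule rise replaced a ratio of group means that rested on a single N2 library, after those sums were seen. Rules voiding the sperm protein comparison when over 50% of its records had no counts, or when no member passed the count filter, were also added after its sums were seen. Whether the replicate numbers pair the libraries was checked from the correlation of deviations from the group means across records, which are not independent. It was 0.456, 0.356 and 0.186 for replicates 1, 2 and 3, all above 0.1, and -0.372 to 0.0903 for the other combinations. The numbers were thus treated as pairing the libraries, on the data alone and only in the fits with the block. The main tests hold no block. The fit with the block called 5129 records, within 1.5 times the 3773 without it.

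The scripts were tested on simulated data for spr-5; met-2 against N2, with 200 records changed. Of 14243 records tested, edgeR recovered 26.9% of those changed 2-fold and 76.3% of those changed 4-fold, with 10.0% of its calls false. DESeq2 recovered 50.5% and 87.5% with 29.0% of its calls false. A simulated list of 30 genes raised 2-fold passed in camera (adjusted p = 3.20e-36, and 0.00456 with an estimated correlation), and 0 of 35 other lists did. The simulated counts were drawn independently for each gene, so they hold no correlation between genes. In the real libraries the estimated correlation of a list reached 0.885, for ribosomal protein genes. The 0 of 35 therefore does not show how often camera would call lists falsely here.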

Results

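Whole-animal RNA was sequenced from starved first-stage (L1) larvae of the nematode Caenorhabditis elegans. Libraries came from 2 groups of 3 replicates each, the wild-type strain N2 and the progeny of animals mutant for both spr-5 and met-2. SPR-5 is a histone H3 lysine demethylase of the LSD1 family and MET-2 a histone H3 lysine methyltransferase of the SETDB1 family. The stated purpose of the comparison was to find genes expressed differently in the double mutant larvae. The N2 libraries held 22014739, 21127829 and 20010959 counts for replicates 1, 2 and 3, and the spr-5; met-2 libraries 18065786, 17062557 and 25368364. The first principal component of log2 CPM (counts scaled to library size) separated all 3 libraries of each group from the other group. Nothing in the labels says whether replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

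The mutated genes were examined at the start, because their counts could check the labels. Counts of spr-5 were higher in the mutant group, at 123 ± 6.58 CPM (SD, n = 3) against 53.8 ± 10.7 CPM in N2, a log2 fold change of 1.19 ± 0.16 (SE, edgeR adjusted p = 0.00132). Counts of met-2 were slightly lower, at 82.7 ± 4.04 against 111 ± 9.36 CPM, a log2 fold change of -0.43 ± 0.11 (SE, edgeR adjusted p = 0.0290). The met-2 difference missed the threshold without N2 replicate 3 (edgeR adjusted p = 0.0572), without spr-5; met-2 replicate 2 (0.0976) and without spr-5; met-2 replicate 3 (0.127). It also missed the threshold without a count filter (0.0716) and with library size only (0.286), where the log2 fold change was -0.20. All alternatives together ranged from 0.00484 to 0.286. Neither transcript was lost, and the counts of whole transcripts do not show which part of a gene an allele removes, so they check no label. All directions below are therefore those of the libraries labelled spr-5; met-2.

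The libraries labelled spr-5; met-2 differed widely from N2. Of 14557 transcript records tested, 3773 (25.9%) changed at an adjusted p below 0.05 in edgeR's quasi-likelihood test, 2075 rising and 1698 falling. These covered 1819 rising and 1492 falling named genes among 12461 tested. Rises were larger than falls, with 1465 rising and 696 falling records past 2-fold, 849 and 175 past 4-fold, and 491 and 46 past 8-fold. The 3 libraries of one group lay wholly beyond the 3 of the other in 6342 records (43.6%), where chance gives 10%. The count of changed records was 2429 without spr-5; met-2 replicate 2 and 2210 without its replicate 3, and the count falling was 1121 without N2 replicate 2, 918 without spr-5; met-2 replicate 2 and 800 without spr-5; met-2 replicate 3. Scaling by library size only moved the median log2 fold change of all records from -0.01 to 0.21 and the rising share of calls from 55.0% to 77.7%, with 2882 rising and 827 falling.

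Genes of the germline were higher in the mutant larvae. The 5 germline gene lists all moved up. Of 15 tested components of P granules, the RNA and protein condensates of germ cells, 11 rose and 0 fell (13 and 0 when adjusted over the list alone), with a median log2 fold change of 2.30 (camera adjusted p = 5.69e-10, and adjusted p = 0.232 with an estimated correlation). Among them the RNA helicase gene glh-1 went from 44.9 ± 13.2 to 566 ± 31.2 CPM (SD, n = 3 per group), a log2 fold change of 3.66 ± 0.22 (SE, edgeR adjusted p = 3.04e-05). The Piwi gene prg-1 went from 27.6 ± 2.79 to 636 ± 11.7 CPM, a log2 fold change of 4.52 ± 0.14 (SE, edgeR adjusted p = 6.49e-06). The P granule gene deps-1 rose by 4.68 ± 0.34 and the Argonaute gene wago-4 by 3.26 ± 0.18 on the log2 scale (SE). The record matched to pgl-1 was not among those tested. Of 26 meiotic chromosome genes, 19 rose and 1 fell (20 and 2 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 5.89e-08, and adjusted p = 0.217 with an estimated correlation). The HORMA domain gene htp-1 rose from 3.76 ± 0.743 to 50.1 ± 3.67 CPM, a log2 fold change of 3.74 ± 0.19 (SE, edgeR adjusted p = 1.67e-05), and the synaptonemal complex gene syp-1 by 3.37 ± 0.16. The member that fell was zhp-4, at -1.60 ± 0.31, named here after its value was seen; its record overlaps pro-3 on the same strand.

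The other germline lists followed the same direction with smaller medians. Of 17 genes for germline proliferation and RNA regulation, 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 0.000363, and adjusted p = 0.217 with an estimated correlation), among them the translational regulator gene gld-1 at 1.99 ± 0.19 and daz-1 at 2.33 ± 0.16 (log2 fold change, SE). Of 21 oocyte and maternal genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 1.25 (camera adjusted p = 2.43e-06, and adjusted p = 0.341 with an estimated correlation), led by mex-5 at 4.19 ± 0.22 and the Y-box gene cey-2 at 3.97 ± 0.39. The spermatogenesis list names 33 genes, of which 32 had a record and only 13 passed the count filter. Of these 13, 6 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.65 (camera adjusted p = 0.000721, and adjusted p = 0.217 with an estimated correlation). The risers included the kinase gene spe-6 at 3.95 ± 0.27 and cpb-1 at 3.69 ± 0.28, a gene that went from 0.816 ± 0.293 to 10.6 ± 0.608 CPM. Other risers were near 0 in N2, with snf-10 at 0.0682 ± 0.0278 CPM against 1.01 ± 0.109 in spr-5; met-2, and peel-1 at 0.186 ± 0.0710 against 1.72 ± 0.195. Members that pass the filter only through spr-5; met-2 can hardly be called as falling. On voom values the spermatogenesis median was 0.64, and 1.13, 1.35 and 1.19 without N2 replicates 1, 2 and 3, 1.38 without spr-5; met-2 replicate 1, 0.53 without spr-5; met-2 replicate 2 and 0.39 without a count filter. The proliferation median was 0.88, and 0.41 without N2 replicate 3. Over the other alternatives the adjusted p of the 5 lists lay between 1.79e-14 and 0.00591. The rising members stood at similar levels in all mutant libraries, with medians of 1.03, 1.01 and 0.959 times the 3-library mean for P granule genes in replicates 1, 2 and 3.

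**Figure D1:**
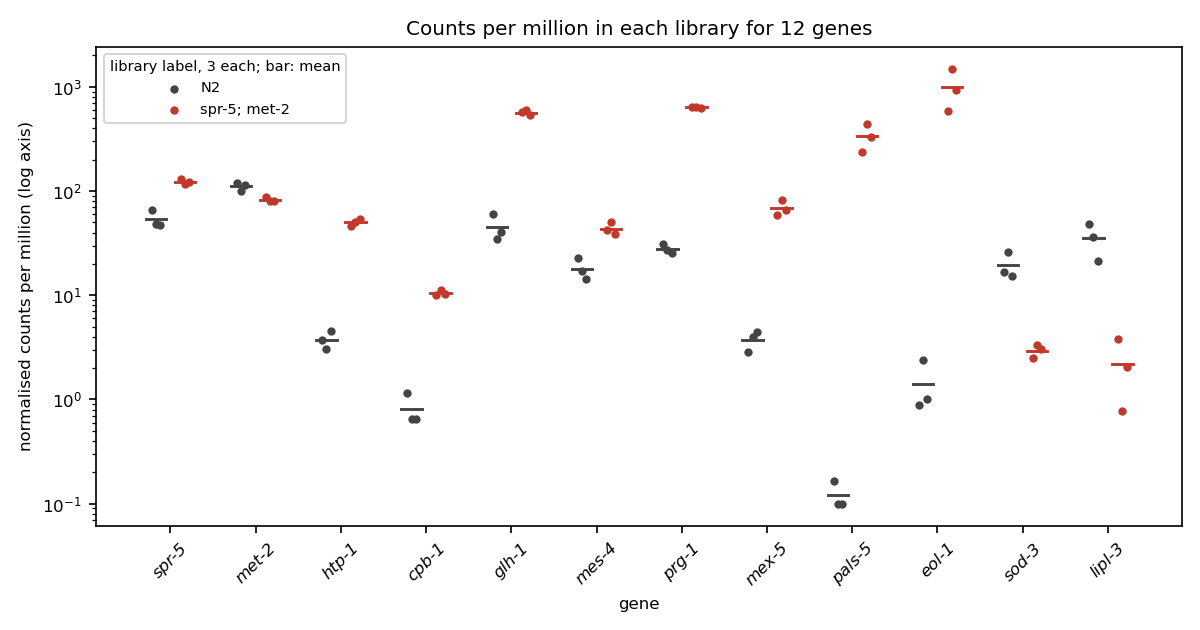
Normalised CPM on a log axis for 12 genes, with 3 points per group (N2 in grey, spr-5; met-2 in red) and a bar at each mean. The germline genes htp-1, cpb-1, glh-1, mes-4, prg-1 and mex-5 and the pathogen response genes pals-5 and eol-1 lie higher in every spr-5; met-2 library than in any N2 library, and sod-3 and lipl-3 lie lower.

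Small RNA and cell cycle genes also moved up, and some chromatin genes rose. Of 35 small RNA pathway genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 fold change of 0.90 (camera adjusted p = 1.48e-07, and adjusted p = 0.217 with an estimated correlation). Several of these are germ granule genes counted above, such as prg-1 and wago-4, and others were the Argonaute gene ppw-1 at 4.17 ± 0.25 and tofu-4 at 2.91 ± 0.18 (SE). Of 31 cell cycle and DNA replication genes, 14 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 3.70e-06, and adjusted p = 0.341 with an estimated correlation). The kinetochore gene knl-1 rose by 1.13 ± 0.14 and the cyclin gene cya-1 by 0.84 ± 0.13. Over the other alternatives the adjusted p lay between 5.28e-11 and 0.000354 for small RNA genes and between 5.71e-08 and 0.00395 for cell cycle genes. Of 28 histone H3 methylation genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.0315, and adjusted p = 0.341 with an estimated correlation). The risers held spr-5 itself, the methyltransferase gene set-32 at 2.04 ± 0.24 and mes-4, a germline methyltransferase gene, at 1.28 ± 0.20 (SE, edgeR adjusted p = 0.00339), and the member that fell was met-2. Of 15 DREAM complex and synMuv B genes, 6 rose and 1, met-2, fell (8 and 1 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 0.0361, and adjusted p = 0.550 with an estimated correlation). The retinoblastoma gene lin-35 rose from 30.6 ± 0.179 CPM in N2 to 67.8, 102 and 69.9 CPM in replicates 1, 2 and 3 of spr-5; met-2, and the zinc finger gene lin-13, which is on both lists, by 1.07 ± 0.14 (log2, SE). The genes lin-61, which rose as well, met-2, hpl-2 and lin-65 are also on both lists, so these results overlap. The last 2 list calls were lost without N2 replicate 3 (adjusted p = 0.101 for both) and without spr-5; met-2 replicate 2 (0.0772 for histone methylation and 0.0565 for DREAM), and the histone methylation call also without spr-5; met-2 replicate 1 (0.0551). The voom median of the histone methylation list was 0.24, and 0.13 without N2 replicate 1. Removing a trend with gene length ended both as well (0.168 and 0.0679). Over all alternatives the adjusted p lay between 0.00888 and 0.341 for histone methylation and between 0.00574 and 0.550 for DREAM.

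Of all lists, the highest median was that of the pals family, genes of the intracellular pathogen response to microsporidia and virus. Of 31 tested pals genes, 27 rose and 0 fell (29 and 0 adjusted over the list alone), with a median log2 fold change of 6.27, the same value when the 3 members with 0 counts in N2 were set to their bound (camera adjusted p = 4.52e-18, and adjusted p = 0.271 with an estimated correlation). Over the other alternatives the adjusted p lay between 7.50e-24 and 0.00238. The gene pals-5, at 0.121 ± 0.0377 CPM in N2 (SD, n = 3), had a log2 fold change of 11.38 ± 0.39 (SE, edgeR adjusted p = 6.49e-06). Summed over the family, pals records held 5015, 10698 and 7849 CPM in replicates 1, 2 and 3 of spr-5; met-2 and 155, 211 and 185 CPM in those of N2. The rising members stood at 0.680, 1.32 and 0.985 times their mean in the 3 mutant libraries, a wider spread than that of the germline genes. The RNA decapping enzyme homologue eol-1, of the same response, rose by 9.45 ± 0.56 (SE), and by 10.04 without N2 replicate 2. The 2 family members known as antagonistic regulators of the response, named here after their values were seen, did not pass: pals-22 was at 0.48 ± 0.17 (edgeR adjusted p = 0.0730) and pals-25 at -0.09 ± 0.14 (edgeR adjusted p = 0.678). The wider list of innate immune and pathogen response genes went both ways, with 14 of 44 rising and 13 falling (16 and 17 adjusted over the list alone), a median of -0.32, a voom median that turned to 0.02 with library size only, a mean of 1.27, an upward camera direction and no list call (camera adjusted p = 0.704). Against no change, and not against other genes, it passed with fry (adjusted p = 0.0126), while the camera alternatives gave 0.523 to 0.849. Pals genes are close paralogs with overlapping neighbours, so single members are uncertain where reads could be shared.

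Genes with F-box and MATH domains, large families of candidate ubiquitin ligase adaptors, were also higher as lists, with some members falling. Of 103 F-box A genes, 50 rose and 6 fell (52 and 8 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 1.97e-07, and adjusted p = 0.341 with an estimated correlation). Of 48 MATH and BATH domain genes, 29 rose and 3 fell (33 and 3 adjusted over the list alone), with a median of 1.46 (camera adjusted p = 8.07e-10, and adjusted p = 0.217 with an estimated correlation). The gene fbxa-7 rose by 8.31 ± 0.46 and bath-2 by 4.14 ± 0.19 on the log2 scale (SE). Over the other alternatives the adjusted p lay between 3.04e-08 and 0.00674 for F-box A and between 8.30e-15 and 0.000945 for MATH and BATH genes. Their paralogs also leave single members uncertain. In the mutant libraries the rising F-box A genes stood at 0.777, 1.22 and 0.994 times their mean and the MATH and BATH genes at 0.804, 1.15 and 1.01 times.

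Of the 10 largest rises among records reaching 5 CPM, 7 had 0 counts in all N2 libraries, so their folds are lower bounds against 3 counts over the N2 group, covering counting error only. The uncharacterised genes F15H10.10 and F15H10.9 were at least 1885-fold and at least 398-fold higher. The pals genes pals-3, pals-11 and pals-10 were at least 976-fold, at least 515-fold and at least 396-fold higher, math-5 at least 733-fold and T13B5.9 at least 8.62 on the log2 scale. With 2 counts in N2 against 11778, fbxa-75 was 5240.5-fold higher (95% exact interval 1450.4 to 43277). The channel-family gene trpl-5, with 1 count in N2 against 4359, was 3879-fold higher (95% exact interval 696 to 153250), and its 1 count was in N2 replicate 1. The last of the 10 was pals-28, at 301 ± 91.7 CPM in spr-5; met-2 against 0.0991 ± 0.172 CPM in N2, with 6 N2 counts all in replicate 2. Leaving out these N2 libraries moved the fitted log2 fold changes from 11.55 to 13.52 for trpl-5 and from 11.43 to 15.61 for pals-28, and math-5 was fitted at 12.03 without spr-5; met-2 replicate 2 against 12.64. The lowest fitted values were 10.85 for trpl-5, without spr-5; met-2 replicate 2, and 10.84 for pals-28, without N2 replicate 3.

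Among the 10 largest falls were aspartyl protease genes, lipid genes and an F-box gene. With 2 counts in spr-5; met-2 against 433 in N2, fbxa-185 was 243-fold lower (95% exact interval 66.9 to 2015). The protease genes asp-16 and asp-17 were at -6.21 ± 0.79 and -4.45 ± 0.30 (log2 fold change, SE), with asp-16 at -5.37 without N2 replicate 1 and -7.13 without spr-5; met-2 replicate 1. The carnitine palmitoyl transferase gene cpt-3 was at -4.30 ± 0.82, with -3.49 without N2 replicate 1 and -5.47 without spr-5; met-2 replicate 1. The lysosomal lipase gene lipl-3 went from 35.1 ± 13.6 to 2.19 ± 1.51 CPM (SD, n = 3), with a log2 fold change of -4.59 without spr-5; met-2 replicate 1. The remaining 5 were pud-3 at -5.98 ± 1.14, which limma voom did not call and which was at -4.69 without N2 replicate 2, Y44A6D.5 at -5.36 ± 0.37, nspg-7.2 at -5.13 ± 0.31, math-45 at -5.05 ± 0.62, and -6.13 without spr-5; met-2 replicate 1, and W04E12.7 at -4.21 ± 0.33.

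Genes of insulin signalling and starvation arrest were lower. Of 25 tested, 1 rose and 11 fell (1 and 11 adjusted over the list alone), with a median log2 fold change of -0.52 (camera adjusted p = 0.00872, and adjusted p = 0.341 with an estimated correlation; 0.00186 to 0.0183 over the other alternatives). The superoxide dismutase gene sod-3, a target of the DAF-16 transcription factor, went from 19.4 ± 5.89 to 2.94 ± 0.421 CPM, a log2 fold change of -2.72 ± 0.26 (SE, edgeR adjusted p = 0.000276). The gene dod-3 was at -2.76 ± 0.37 and the lipase gene lipl-4 at -2.31 ± 0.34, and the member that rose, the AMP-activated kinase gene aak-1, was at 2.29 ± 0.22. Of 26 insulin-like peptide genes, 3 rose and 11 fell (3 and 11 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 0.000490, and adjusted p = 0.217 with an estimated correlation). The other alternatives gave 1.57e-05 to 0.0101 for this family, and its voom median in the fit with the replicate block was -0.74, and -0.44 with the length trend removed. The peptide gene ins-35 was at -2.84 ± 0.34 and ins-29 at -2.06 ± 0.24. Several insulin-like peptide genes are also on the insulin signalling list, so these results overlap.

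The list medians of ribosomal protein and neuropeptide genes were lower by less than 2-fold. Of 61 ribosomal protein genes, 28 fell and 1 rose (41 and 1 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 3.35e-11, and adjusted p = 0.550 with an estimated correlation). The gene rps-21 was at -0.80 ± 0.15, and the member that rose, rpl-11.1, was at 1.48 ± 0.14. With the length trend removed, rps-21 and rps-24 no longer passed. Of 89 neuropeptide genes, 51 fell and 0 rose (59 and 0 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 1.71e-14, and adjusted p = 0.217 with an estimated correlation). The gene nlp-12 was at -1.30 ± 0.11 and flp-15 at -0.87 ± 0.11. Over the other alternatives the adjusted p lay between 6.97e-19 and 0.0490 for ribosomal protein genes and between 4.99e-18 and 0.00246 for neuropeptide genes. Of 111 C-type lectin genes, 34 fell and 10 rose (36 and 12 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.000893, and adjusted p = 0.388 with an estimated correlation). Members went both ways, with clec-135 at -4.50 ± 0.43 and clec-92 at 3.24 ± 0.20. The other alternatives gave 8.04e-06 to 0.0352.

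**Figure D2:**
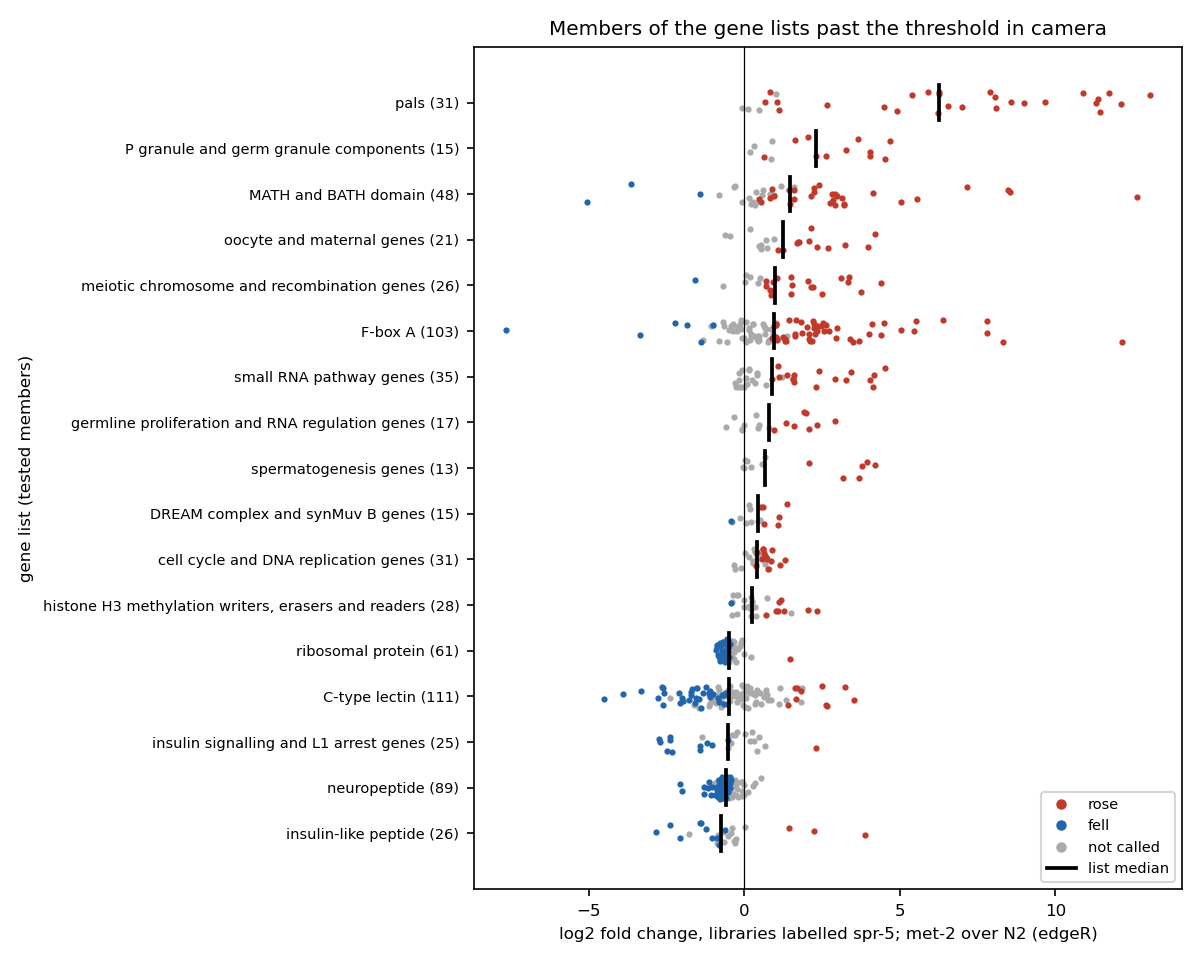
Log2 fold change of spr-5; met-2 over N2 (horizontal axis) for each tested member of the 17 gene lists past the threshold in camera, with members that rose in red, fell in blue and did not pass in grey, and a black bar at each list median. The pals median of 6.27 lies farthest from 0, and members with 0 counts in N2 are drawn at their fitted value, which is not a bound.

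Marker lists of somatic tissues lay near the threshold, passing under some alternatives only, and most of their called members fell. Of 28 intestine genes 4 rose and 12 fell (5 and 12 adjusted over the list alone; median -0.28, camera adjusted p = 0.0520), with the GATA factor gene elt-2 at 1.54 ± 0.24 and the protease gene cpr-5 at -1.16 ± 0.13. Of 25 body wall muscle genes 1 rose and 7 fell (1 and 9 adjusted over the list alone; median -0.31, camera adjusted p = 0.0550), with the troponin gene unc-27 at -0.90 ± 0.12 and the abundant myosin gene unc-54 at -0.07 ± 0.24. Of 18 pharynx genes 0 rose and 6 fell (0 and 6 adjusted over the list alone; median -0.29, camera adjusted p = 0.0520), with tni-4 at -0.91 ± 0.13. Of 38 neuron genes 4 rose and 8 fell (4 and 9 adjusted over the list alone; median -0.19, voom median 0.02 with library size only, camera adjusted p = 0.0613), with the neuropeptide gene flp-14 at -0.80 ± 0.13. Its called members with the smallest adjusted p, flp-14, nlp-21, nlp-15 and flp-18, are all in the neuropeptide family as well. With the replicate number as a block the pharynx (adjusted p = 0.0439) and neuron lists (0.0457) passed, over ranges of 0.0159 to 0.388 and 0.0101 to 0.616 across alternatives. The intestine list passed without N2 replicate 2 (0.0452), without N2 replicate 3 (0.0254) and without spr-5; met-2 replicate 1 (0.00901), within a range of 0.00901 to 0.616, and the muscle list without N2 replicate 2 (0.0233), within a range of 0.0101 to 0.550. The pharynx list passed also without N2 replicate 3 (0.0159) and spr-5; met-2 replicate 3 (0.0292), and the neuron list without N2 replicate 3 (0.0316) and spr-5; met-2 replicate 1 (0.0164). With the length trend removed all 4 passed (0.0289 for intestine, 0.0101 for muscle and neuron, 0.0253 for pharynx). Voom medians were -0.26 for muscle, and -0.10 without N2 replicate 1, -0.28 for pharynx, and -0.50 without N2 replicate 3, and -0.20 for neurons, and -0.32 without N2 replicate 3 and -0.08 without spr-5; met-2 replicate 2. With library size only those of intestine, muscle and pharynx were -0.05, -0.03 and -0.05. With library size only the intestine (0.0256) and pharynx lists (0.0250) passed, with the filter of 1 CPM the pharynx list (0.0363), and with fry, against no change, the muscle (0.0418) and pharynx lists (0.0333). Without a count filter the intestine (0.0132), pharynx (0.0210) and neuron lists (0.0308) passed.

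Epidermal, developmental and stress lists had no list call except under some alternatives. Of 21 hypodermis and seam genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), with che-14 at 1.65 ± 0.21 and grd-3 at -1.07 ± 0.15. Of 32 cuticle and molting genes 1 rose and 0 fell (0 and 0 adjusted over the list alone; median 0.64, camera adjusted p = 0.257). The riser mlt-10, at 1.14 ± 0.28, was not called without spr-5; met-2 replicate 2 or 3 (highest edgeR adjusted p = 0.0655). This list passed with the replicate block (0.0279), without N2 replicate 2 (0.0170) and without spr-5; met-2 replicate 1 (0.0284), as well as with the length trend removed (0.0253), over a range of 0.0170 to 0.830. Its voom median was 0.87, and 0.08 without N2 replicate 1, 1.34 without N2 replicate 2, 1.43 without spr-5; met-2 replicate 1 and 0.31 without spr-5; met-2 replicate 2. Of 8 heterochronic genes 1, lin-46 at 0.93 ± 0.20, rose and 0 fell (1 and 0 adjusted over the list alone), and the abundant member nhl-2 was at 0.20 ± 0.24. Of 13 Hox and lineage genes 0 were called in edgeR, over all records or adjusted over the list alone (median 0.02, voom median -0.16 without N2 replicate 1, mean 0.08, camera direction down, ceh-20 at 0.05 ± 0.11). Of 6 early zygotic genes 1, sdz-6, rose and 0 fell (4 and 1 adjusted over the list alone; median 1.04, camera adjusted p = 0.127), and sdz-6 had 3 counts in N2 against 1214, a 360-fold difference (95% exact interval 123 to 1749), with all 3 counts in N2 replicate 2, without which the fitted log2 fold change moved from 8.38 to 11.63. Without spr-5; met-2 replicate 2 the fitted value of sdz-6 was 7.76. The early zygotic list passed in camera without a count filter (adjusted p = 0.0326, within a range of 0.0326 to 0.445) and, against no change, with fry (0.00674). Of 25 heat shock and stress genes 8 rose and 5 fell (8 and 5 adjusted over the list alone; median -0.06, voom median 0.19 with library size only, mean 0.31, camera direction up), with the glycerol synthesis gene gpdh-1 at 2.77 ± 0.12 and the chaperone gene hsp-12.6 at -2.48 ± 0.45.

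Several large families had members moving in both directions and no list call. Of 105 col collagen genes 11 rose and 27 fell (11 and 27 adjusted over the list alone), with a median of -0.12 (-0.09 on voom values, and 0.14 with library size only), and with col-80 at -2.67 ± 0.16 and col-111 at 4.18 ± 0.26. This family passed without N2 replicate 3 (camera adjusted p = 0.0379) and with library size only (0.00629), within a range of 0.00629 to 0.616, both times as lower than other genes. Of 313 chemoreceptor genes 25 rose and 19 fell (24 and 13 adjusted over the list alone; median -0.11, voom median 0.14 with library size only, mean 0.01, camera direction down), led by sri-31 at 4.82 ± 0.15. Of 171 nuclear hormone receptor genes 6 rose and 22 fell (2 and 8 adjusted over the list alone), with nhr-271 at -2.47 ± 0.38, and this family passed without N2 replicate 2 (camera adjusted p = 0.0165) and with the length trend removed (0.0237, within a range of 0.0165 to 0.616). Of 63 cytochrome P450 genes 4 rose and 11 fell (4 and 11 adjusted over the list alone), with cyp-31A3 at 3.14 ± 0.19 and cyp-37A1 at -1.43 ± 0.22, and the family passed without N2 replicate 2 (camera adjusted p = 0.0481) and without spr-5; met-2 replicate 1 (0.0418), with library size only (0.0252), without a count filter (0.0453) and with the length trend removed (0.0253), within a range of 0.0252 to 0.678. Of 53 UDP-glucuronosyltransferase genes 2 rose and 9 fell (2 and 6 adjusted over the list alone), with ugt-64 at 1.77 ± 0.33. Of 23 histone genes 3 rose and 4 fell (3 and 5 adjusted over the list alone), with the variant gene his-74 at 3.01 ± 0.18 and his-71 at -0.82 ± 0.12. The voom median turned positive for col genes without spr-5; met-2 replicate 1 (0.06), for chemoreceptor genes without N2 replicate 3 (0.04) and for cytochrome P450 genes without spr-5; met-2 replicate 2 (0.01). Of 34 tested small non-coding records 4 rose and 2 fell (3 and 1 adjusted over the list alone), with 21ur-6424 at 3.55 ± 0.67, and 4.74 without N2 replicate 3.

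Rising records were scarce on the X chromosome, where germline-expressed genes are known to be few. Of 1773 tested X-linked records 89 (5.02%) rose, against 1711 of 10691 autosomal records, an odds ratio of 0.277 (95% interval 0.220 to 0.346, two-sided Fisher's exact test, p = 1.14e-41). The rising share ran from 12.5% on chromosome V to 18.3% on chromosome II, with htp-1 on IV, cpb-1 on III and glh-1 on I. Falling records were somewhat more frequent on X, at 244 (13.8%) against 1183 (11.1%), an odds ratio of 1.28 (95% interval 1.101 to 1.49, two-sided Fisher's exact test, p = 0.00126). Neighbouring genes are not independent, so these p-values are too small by an unknown amount. The difference in falls did not pass with library size only (odds ratio 1.102, Fisher's exact test, p = 0.369) or without a filter on low counts (1.13, p = 0.106).

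**Figure D3:**
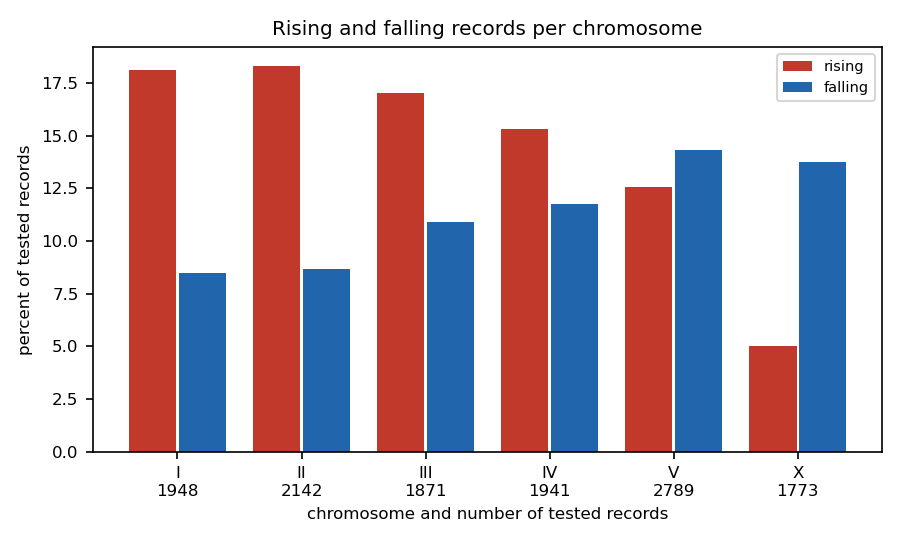
Bars from 0 give the percent of tested records per chromosome that rose (red) or fell (blue) in spr-5; met-2, with the number tested under each chromosome. The rising share on X, 5.02%, lies below that of every autosome, of which V is the lowest at 12.5%.

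The authors' deposited table gave nearly the same calls as the counts, with smaller rises for some genes with few N2 counts. The authors' deposited table called 4223 records below an adjusted p of 0.05, 2330 rising and 1893 falling. Of the edgeR calls 3679 (97.5%) were shared in the same direction with the authors' deposited table, which is 87.1% of the table's calls, and 0 had the opposite direction by edgeR and by the authors' DESeq2. For glh-1 the authors' deposited table gave a log2 fold change of 3.59 against 3.66 in edgeR. It gave 4.25 for pals-28 against 11.43 and 5.21 for sdz-6 against 8.38. For F15H10.10 and math-5, with 0 counts in N2, it gave 7.46 and 6.04, under the bounds of at least 10.88 and at least 9.52 on the log2 scale. The sources used here do not say whether the deposited fold changes were pulled toward 0 where counts are few. The values may thus be unlike measures, and the gaps show no conflict with the counts. The shared count was 2413 without spr-5; met-2 replicate 2 and 2199 without its replicate 3.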

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

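No result past its threshold changed direction under any alternative run. A trend with exonic length and records summed per gene were added after the data were seen. The count of changed records was 3773, and 2161 with a 2-fold minimum, 1879 at an adjusted p below 0.01, and 2210 to 3849 with a library left out. The count rising was 2075, and 1214 at an adjusted p below 0.01 and 1410 to 2046 with a library left out. The count falling was 1698, and 827 with library size only, 696 with a 2-fold minimum, 665 at an adjusted p below 0.01, and 800 to 1803 with a library left out. Stricter thresholds call fewer records by construction, and the spread with a library left out was not explained; for library size only the scaling shift of 0.21 moves calls upward. The odds ratio for falls on X was 1.28, and 1.102 with library size only and 1.13 without a count filter; the cause was not tested. Calls shared with the authors' deposited table numbered 3679, and 2199 to 3341 with a library left out. Of 35 lists 17 passed in camera, and 0 with an estimated correlation (7 at an unadjusted p under 0.05), and 15 to 22 with a library left out. Estimated correlations ran from -0.030 for spermatogenesis to 0.885 for ribosomal protein genes, against the preset 0.01. A higher correlation weakens a list test. The spermatogenesis list, whose estimated correlation lies below the preset, went from an unadjusted camera p of 0.000268 to 0.0182 and lost its call. A higher correlation cannot account for that. The estimated setting thus differs in more than the size of the correlation, and the lost calls do not show the effect of correlation alone. With the replicate numbers as a block for the pairing, 5129 records were called, 3759 of the 3773 were kept in the same direction, and the pharynx, neuron and cuticle lists gained a call; it changed no other list or named-gene call. The length trend left 4907 records called and 22 lists. Of the named genes 155 had the same call with DESeq2 and 154 with limma voom. Limma voom for lists was not run apart, since camera already used voom values. In the simulation edgeR recovered 26.9% of changes of 2-fold, but far fewer records were changed there than the 3773 called here. The adjusted p depends on how many records change, so this share does not give the recovery in these libraries. How many changes near 2-fold were missed here is not known, and a missed call shows no absence of change.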

Other observations

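In this part, the tests on vitellogenin, early zygotic genes, gene length, pals gaps, members of the pathogen response outside the pals family and library scaling were chosen after the results were seen, and those on major sperm protein, fasting genes, listed genes on X and other splits before.

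The higher germline genes may reflect transcription in the larvae or RNA from other material. Adults left in the preparation would bring abundant vitellogenin mRNAs. These reached at most 14.7 CPM in a spr-5; met-2 library, 1.03% of the rise of 1425 CPM in the P granule list. N2 replicate 3 stood apart from the other N2 libraries at 72.5 CPM. Only 4 of the 6 vitellogenin genes had a record, and reads that fit several records may be missing from the sum. The low sum thus argues against adults in the mutant libraries only as far as these records capture vitellogenin reads. Sperm-bearing gonads stay open, because the major sperm protein records (log2 ratio -0.56) are near-identical, 12 of 25 had 0 counts in all libraries and none passed the count filter. A length trend removed per library left all 5 germline lists called, with a lowest median of 0.61. Unhatched embryos also stay open, because the 6 tested early zygotic genes had a median of 1.04, as does an effect of the mutations in germ cells or soma, since whole larvae were sequenced.

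The rise of the pals family may come from the mutations or from a difference between cultures. A single library does not account for it, because 23 of the 27 rising records kept at least a 2-fold gap between the lowest spr-5; met-2 and the highest N2 library. The 5 members of the same response examined outside the family, eol-1, skr-3, skr-4, skr-5 and cul-6, named after their values were seen, all rose (5 of 5). An infection of the mutant cultures and a genetic effect on the response cannot be told apart, because each genotype was grown as its own cultures. The study design names the genotype as the biological difference, and it stays untested.

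The lower ribosomal protein and neuropeptide genes could reflect scaling, gene length or biology. A factor per library moves a list and all records alike, so the gap between their medians with library size only (the smaller was -0.48) decides nothing about scaling. In the fit with the replicate block, removing the length trend moved the neuropeptide voom median from -0.62 to -0.36 and the list stayed called (adjusted p = 5.65e-08), against length as the whole cause. The ribosomal protein voom median moved from -0.50 to -0.29, just above the bound of -0.3, and the list stayed called (camera adjusted p = 2.13e-05). Length may thus account for part of either fall, and how much is left open. The genotype stays an untested explanation.

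A hypothesis that the mutant larvae mounted a weaker fasting response was tested on 8 fasting-linked genes not examined before, of which 6 could be tested. Their median log2 fold change was -0.23 and the set did not pass in camera, with cpt-4 at 2.07 ± 0.23 and fil-1 at 1.56 ± 0.18 against fil-2 at -2.21 ± 0.37, acs-11 at -0.80 ± 0.20 and lipl-2, not past the threshold, at -1.04 ± 0.33 (SE). The genes went both ways, so the test does not decide, and the lower sod-3, lipl-3 and cpt-3 may belong to something narrower. A second hypothesis, that listed germline genes and autosomal families alone make rises scarce on X, was tested by leaving out every listed gene. Of 1643 other X-linked records 83 rose, and the odds ratio was 0.291 (95% interval 0.229 to 0.366, Fisher's exact test). The listed genes alone thus do not account for the scarcity. Most tested records, 10815, are on no list, so leaving out the listed genes could move the odds ratio only little. Germline genes outside the lists stayed in, and the test says nothing about them.

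The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one puts both genotypes in each group, so any genotype difference adds to the spread within groups. Low counts of called records there follow from that, and they lend the real split no support. The real split called 3773 records and the highest other split 0 by edgeR, with 59 to 645 records at an unadjusted p under 0.05 in the other 9, and 0 by limma voom, so 1 of 10 splits gave as many. Among the 4 splits that part all 3 numbered pairs, the fit with the block called 5129 records for the real one and at most 0 for the others. For an odds ratio of rises on X as far from 1, 1 of 10 splits, the real one at 0.277, gave any, since the others called no records. For gene lists the real split called 17 and the highest other 21, with 4 of 10 splits calling as many. Among the splits parting all pairs the highest other called 17. Every other split also keeps part of the contrast, with 2 libraries of a genotype against 1. Its list calls are therefore not free of the genotype difference, and the splits do not decide the list calls. Those calls rest on camera's preset setting, since 0 passed with an estimated correlation, a setting that differs in more than the size of the correlation. Called members of a list are not independent of each other either.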
